A study of Mus musculus with 32 samples.

How the data were processed

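Gene counts were analysed for 32 RNA sequencing libraries of sorted mouse bone marrow cells, 16 of LSK cells and 16 of MEP cells. Per the labels' protocols, cells were sorted into TriZOL, RNA was isolated with the Direct-Zol kit, and paired-end libraries were made with the Takara HT-Seq kit. Per the submitters' processing notes, STAR and featureCounts were used with the mm10 build, and the deposited values are raw counts per gene symbol for each library. The versions of those tools, the gene annotation, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Genes that overlap, antisense partners and near-identical family members, such as the globin, histone, Serpina3, Gbp and Hspa1 genes, can therefore hold each other's reads.

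The table held 33924 genes, of which 933 had no count in any library, and no entry without a gene name. Groups were taken from the titles and characteristics of the samples, which give the cell type, treatment, day and batch. Total counts ran from 13392754 (13.4 M) to 28838622 (28.8 M) in LSK vehicle A. In the same unit they were 12.4 to 21.3 at tamoxifen day 3, 16.1 to 18.3 at day 7, 28.3 to 39.3 in vehicle C and 26.5 to 49.7 under ruxolitinib. In MEP cells they were 20.7 to 24.1, 21 to 27.1, 11.2 to 20.1, 34.4 to 39.7 and 40.3 to 55.5 M. Deeper libraries measure low genes more precisely, and batch C was the deeper batch. Libraries of a group were compared before averaging with a chi-square statistic per degree of freedom over genes, which is about 1 for sampling noise alone. The lowest value over pairs within a group was 13.1, which is more than sampling noise. Vehicle libraries of the same animal number in batches A and C also gave 42.2 to 95.1. The statistic therefore cannot tell separate animals from repeated libraries of an animal. Each library was counted as its own replicate, as the numbers in the labels differ within a group. The labels number animals and do not say how litters or sorting days were shared.

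The vehicle libraries of batch C carry the same animal numbers as vehicle libraries of batch A, 12 and 18 in LSK cells and 12, 32 and 33 in MEP cells. Deviations from the group means correlated across batches within a number at 0.53 and 0.65 in LSK cells and at 0.56, 0.53 and 0.06 in MEP cells, and the chi-square statistic between such libraries was 42.2 to 95.1. The differences between batches correlated between pairs at 0.33 to 0.69 over 9065 genes, with 75.5% of their variation on the first factor. These pairs were used to give each named gene a mean shift between batches without treatment.

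Each comparison was tested with edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3), two-sided, with TMM factors, filterByExpr at a minimum count of 10, and Benjamini-Hochberg adjustment over the genes tested at 0.05. Comparisons within a cell type were contrasts in a fit of its 16 libraries with a mean per group, and those between cell types in a fit of all 32. LSK and MEP libraries of the same animal number were treated as independent in that fit. The filters left 26930 genes in LSK cells, 25274 in MEP cells and 28378 in the joint fit. Values called log2 changes are fitted log2 fold changes with their standard errors, and CPM values are means over the libraries of a group with their standard deviations. Gene lists, 31 in all covering pathways and cell types, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison. Over the 6 treatment comparisons 98 list tests passed at that correlation, 1 with an estimated correlation and 33 with fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes.

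The samples, lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule names Jak2 first, then for each treatment comparison the 8 largest rises and the 8 largest falls (5 for other comparisons) among called genes with a mean logCPM of at least 2 whose treated libraries all lie on one side of all vehicle libraries, passing over unnamed transcripts and immunoglobulin segments. It adds up to 4 members of each list described and a panel of STAT5 targets. Some genes that it names are not reported here. Gene positions are those of GENCODE M21 on mm10, to which 91.4% of the symbols matched.

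The alternatives were RLE factors, DESeq2 1.42.0, no count filter, the libraries of the compared groups alone, the replicate number as a block, limma voom with the animal number as a random block, pooled vehicle batches, and leaving out each replicate in turn. Chosen after seeing the data were tests over expressed genes alone (mean CPM of at least 10, 9805 genes in LSK, 8161 in MEP and 9259 in the joint fit), the same with an offset for GC content or with a factor from the vehicle pairs, and counts without genes that shifted in all vehicle pairs of the other cell type. A search for genes present in every library of a treatment and near absent elsewhere was also chosen after seeing the data.

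The methods were tested on data simulated from the real means and library sizes. Over 10 draws, edgeR recovered genes changed by 2 on the log2 scale in 53.4% of cases on average for the LSK day 3 comparison, 64.5% for LSK day 7 and 18.5% for LSK ruxolitinib, where the draws ranged from 11.5% to 35.4%. For MEP day 3, day 7 and ruxolitinib it recovered 84%, 74.2% and 77.3%. Unchanged genes made up 3.48%, 2.38%, 1.1%, 5.75%, 6.11% and 4.68% of the edgeR calls in that order on average. They made up 29.3%, 25.1% and 39% of the DESeq2 calls in the LSK comparisons. In the draws each gene varied on its own, without the shifts that many genes share between real libraries. The share of unchanged genes among the real calls can therefore be higher, and was not measured. Changed genes were drawn only from those above a set mean count, so recovery of low genes was not measured either.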

Results

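RNA sequencing counts were obtained from sorted bone marrow cells of mice carrying a reversible activating mutation of the Janus kinase gene Jak2 (Jak2V617F), which drives myeloproliferative neoplasms. Per the labels' protocols, the mutation was switched on ex vivo with Dre recombinase mRNA, the cells were transplanted into lethally irradiated recipients, and tamoxifen then activated Cre to delete the mutant allele. A separate arm received ruxolitinib, an inhibitor of JAK1 and JAK2, for 7 days. The cell types sorted were LSK cells (lineage negative, Sca1 positive, Kit positive), which hold the stem cells and multipotent progenitors, and MEP cells, the megakaryocyte and erythroid progenitors. The 32 libraries fall into 10 groups. In batch A, LSK cells came as 4 vehicle, 3 tamoxifen day 3 and 4 tamoxifen day 7 libraries, and MEP cells as 3, 4 and 3. In batch C, LSK cells came as 2 vehicle and 3 ruxolitinib libraries, and MEP cells as 3 and 3. Total counts per library ranged from 11160696 to 28838622 in batch A and from 26511752 to 55473241 in batch C. Each treatment was therefore compared with vehicle of its own batch. No group that received tamoxifen without carrying the deletable allele is described in the labels, so effects of the drug and of the deletion are not separated by these comparisons. The titles give day 0 for every vehicle library. Comparisons with vehicle therefore do not separate the treatment from the time that passed.

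Jak2 itself (chromosome 19, 29251828 to 29313080 on the plus strand of mm10, a protein-coding gene) passed the test in none of the 6 treatment comparisons. In LSK cells its mean was 22.9 ± 6.49 CPM under vehicle (SD, n = 4), 16.7 ± 1.37 at tamoxifen day 3 (n = 3) and 16.1 ± 1.67 at day 7 (n = 4). In batch C it was 28.8 ± 5.7 under vehicle (n = 2) and 31 ± 1.35 under ruxolitinib (n = 3). In MEP cells it was 16.2 ± 1.7 (n = 3), 17.6 ± 4.09 (n = 4) and 19.2 ± 6.75 (n = 3) for vehicle, day 3 and day 7. In batch C these cells had 28.9 ± 8.64 under vehicle and 21 ± 4.18 under ruxolitinib (n = 3 each). The log2 fold changes were -0.45 ± 0.25 (SE), -0.51 ± 0.23 and 0.1 ± 0.29 in LSK cells for day 3, day 7 and ruxolitinib, with adjusted p of 1, 0.496 and 0.912 in edgeR's quasi-likelihood test. In MEP cells they were 0.12 ± 0.28, 0.24 ± 0.3 and -0.46 ± 0.3, with adjusted p of 1, 0.713 and 0.215 in the same edgeR test. Which part of the gene is removed is not given in the sources used here and the counts cover the whole gene, so the Jak2 level does not test the labels.

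Targets of STAT5, the transcription factor that JAK2 phosphorylates, were then followed through every group. In MEP cells Cish and Osm fell in each of the 3 treatment comparisons, and Socs2 fell at day 3 and under ruxolitinib. Cish (chromosome 9, 107296026 to 107302784, plus strand), a feedback inhibitor of cytokine signalling, averaged 20.5 ± 8.96 CPM under vehicle (SD, n = 3), 0.543 ± 0.287 at day 3 (n = 4) and 1.42 ± 0.362 at day 7 (n = 3). It fell from 22.5 ± 9.63 to 2.42 ± 0.946 under ruxolitinib (n = 3 each). Osm (chromosome 11, 4236420 to 4241026, plus strand), which encodes the cytokine oncostatin M, fell from 48.5 ± 18.1 to 10.9 ± 2.81 at day 3 and 11.9 ± 1.03 at day 7, and from 61.2 ± 8.69 to 31.6 ± 6.32 under ruxolitinib. Socs2 (chromosome 10, 95385362 to 95417180, minus strand), another feedback inhibitor, fell from 19 ± 3.55 to 8.06 ± 2.38 at day 3 and from 18 ± 2.62 to 4.05 ± 1 under ruxolitinib. At day 7 it stood at 11.8 ± 4.24 and did not pass the test. In LSK cells Cish averaged 22.9 ± 8.32 under vehicle, 5.71 ± 1.78 at day 3 and 7.5 ± 3.38 at day 7, neither of which passed the test. Socs2 fell from 67 ± 11.5 to 20.9 ± 6.8 at day 7 (n = 4 each).

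**Figure D1:**
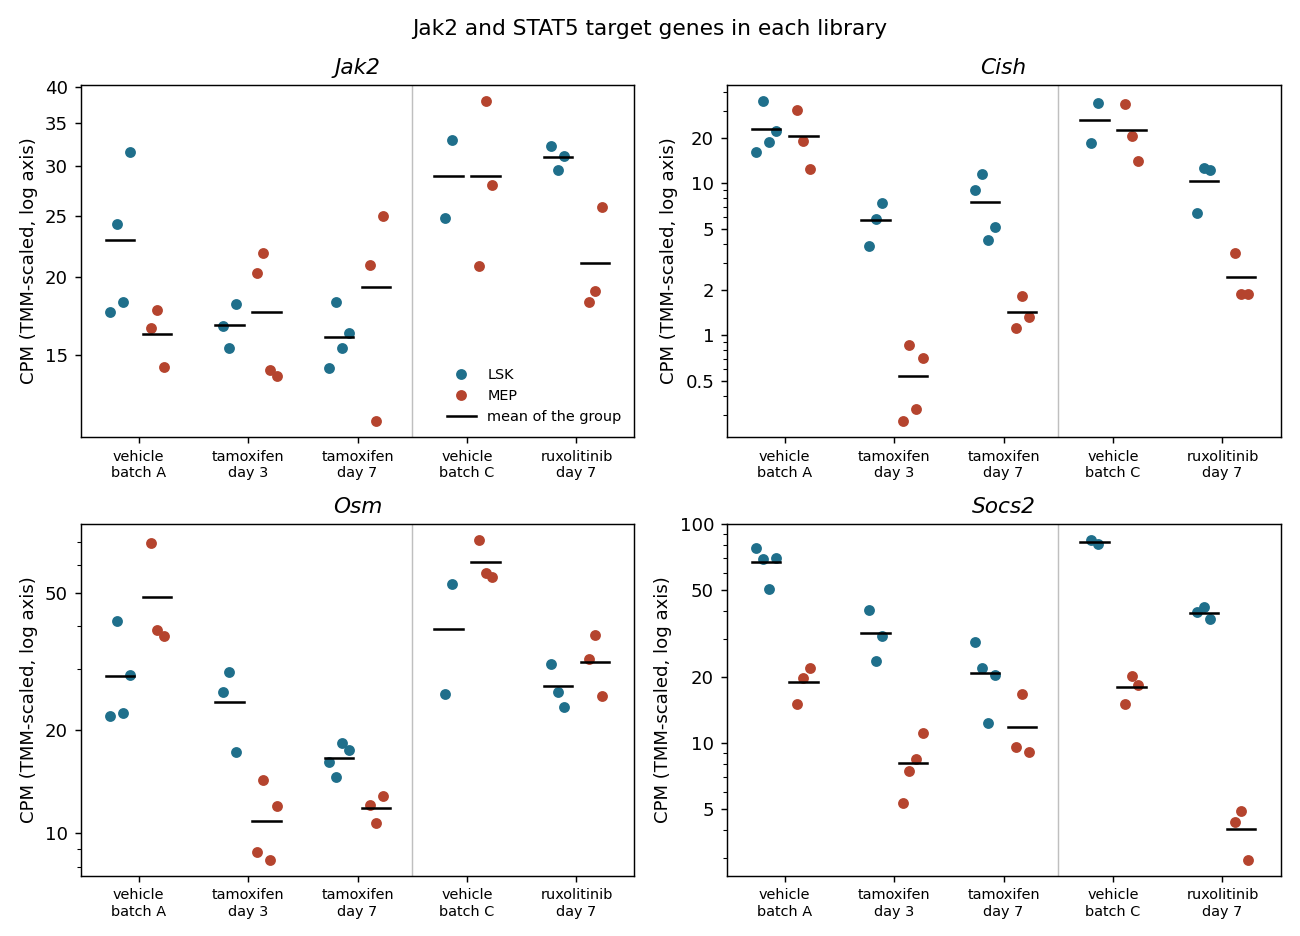
CPM of Jak2 and of the STAT5 targets Cish, Osm and Socs2 on log axes, with a point per library, LSK cells in blue, MEP cells in red, a black line at the mean of each group, and a grey line between batches A and C. In MEP cells the mean of Cish goes from 20.5 under vehicle to 0.543 at tamoxifen day 3, and from 22.5 to 2.42 under ruxolitinib.

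MEP and LSK cells were first compared under vehicle in batch A, which describes the sort. Erythroid genes were higher in MEP cells, among them Rhag, a red cell membrane protein (log2 difference 4.08 ± 0.42, SE), Cldn13 (4.54 ± 0.53) and Tfrc, the transferrin receptor (3.4 ± 0.37). On the erythroid list 31 of 41 erythroid genes were higher with 0 lower. Ly6a, which encodes the Sca1 antigen used to gate LSK cells, was lower by -12.26 ± 0.85, and Elane, the neutrophil elastase gene of granulocyte progenitors, by -8.75 ± 0.72. Of 40 stem cell genes 32 were lower and 1 higher. Of 39 megakaryocyte and platelet genes 29 were lower, including Itga2b (-4.6 ± 0.43) and Meis1 (-5.28 ± 0.46). Of 30 granulocyte and monocyte progenitor genes 29 were lower. Adjusted over the list alone, these counts were 32 higher and 1 lower for the erythroid list, 1 and 34 for the stem cell list, 0 and 31 for the megakaryocyte list, and 0 and 29 for the granulocyte list. Each of these 4 lists passed the camera test, with an adjusted p of at most 2.18e-28, and kept an adjusted p between 0.000605 and 0.00166 with an estimated correlation. edgeR's quasi-likelihood test called 4941 of 28378 genes, 2468 higher and 2473 lower in MEP cells (n = 3 and 4). The median over all genes was -0.27.

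At day 3 of tamoxifen, some STAT5 targets and cholesterol synthesis genes fell in MEP cells and some interferon-stimulated genes rose, which addresses the early effect of deleting the mutant allele. Cish fell by 5.23 ± 0.45 on the log2 scale (SE; edgeR adjusted p = 9.32e-08), Podxl (chromosome 6, 31519488 to 31563981, minus strand), which encodes a sialomucin of the cell surface, by 5.04 ± 0.31 (edgeR adjusted p = 3.52e-10), and Tfrc by 2.42 ± 0.27 (edgeR adjusted p = 7.21e-06), from 2610 ± 524 to 489 ± 155 CPM. B3gnt7, Gab2, Cda and Fam124a also fell, with log2 changes of -4.79 ± 0.45, -4.47 ± 0.48, -3.91 ± 0.36 and -3.73 ± 0.38. The red cell genes Hbb-b2 (-3.95 ± 0.56) and Slc4a1 (-4.51 ± 1.03) fell as well. For the last, the vehicle libraries spanned 6.01 to 220 CPM. The counts of Hbb-b2 are uncertain because its sequence is nearly that of the other adult beta globin gene. Irf7, a transcription factor of the interferon response, rose by 2.16 ± 0.3 from 25 ± 6.96 to 112 ± 34.3 CPM, and Rtp4 by 2.84 ± 0.52 from 6.18 ± 4.4 to 44 ± 23.7 CPM (n = 3 vehicle and 4 treated).

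By list at day 3 in MEP cells, 5 of 31 STAT5 and cytokine-induced targets fell and 0 rose: Podxl, Cish, Osm (-2.16 ± 0.26), the cyclin gene Ccnd2 (-1.59 ± 0.25) and Socs2 (-1.23 ± 0.3). Adjusted over the list alone 8 fell (camera adjusted p = 1.63e-09, and adjusted p = 0.13 with an estimated correlation). The other panel members Pim1, Bcl2l1, Id1, Socs3 and Myc had log2 changes of -0.61 ± 0.51, -0.41 ± 0.22, -1.97 ± 0.79, -0.11 ± 0.82 and 0.31 ± 0.28, and none passed. Among 44 interferon-stimulated genes 10 rose and 0 fell, with Isg15 (2.13 ± 0.42) and Oasl1 (1.37 ± 0.26) beside Irf7 and Rtp4. Adjusted over the list alone 23 rose and 1 fell (camera adjusted p = 1.12e-26, and adjusted p = 0.13 with an estimated correlation). Of 25 cholesterol synthesis and uptake genes 5 fell, including Mvd (-1.37 ± 0.26) and Cyp51 (-1.07 ± 0.24). There 6 did so adjusted over the list alone (camera adjusted p = 8.6e-14, and adjusted p = 0.174 with an estimated correlation). Of 24 integrated stress response genes Mthfd2 (-1.69 ± 0.23) and Trib3 (-1.98 ± 0.41) fell. There 7 did so adjusted over the list alone (camera adjusted p = 1.06e-07, and adjusted p = 0.174 with an estimated correlation). The JAK and cytokine receptor list had 3 of 28 members higher, Stat5b (1.13 ± 0.27), Jak1 (1.46 ± 0.37) and Jak3 (1.28 ± 0.32). Their shifts between vehicle libraries of the same animal number, without treatment, were 0.74, 1.54 and 0.52. There were 6 members higher adjusted over the list alone (camera adjusted p = 0.000718, and adjusted p = 0.282 with an estimated correlation).

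In all, edgeR's quasi-likelihood test called 306 of 25274 genes at day 3 in MEP cells, 224 higher and 82 lower. When only expressed genes were tested it called 773 of 8161. The largest rises included Apoe (4.74 ± 0.69), Ier2 (3.18 ± 0.58), Maf1 (3.06 ± 0.54), the erythroid transcription factor gene Klf1 (2.77 ± 0.54) and Creg1 (2.77 ± 0.57). These 5 genes were also higher, by 2.61, 2.67, 2.62, 2.64 and 2.29, in the batch C than in the batch A vehicle libraries of the same animal numbers, with no treatment between them. The shift of Irf7 and Rtp4 between those libraries was 0.59 and 0.25. Of the 203 genes called higher that could be followed in the LSK vehicle pairs, 38.9% had shifted by over 1. The call count fell to 111, 132 or 177 without tamoxifen replicate 2, 3 or 4, and to 110 or 98 without vehicle replicate 1 or 3. With the GC offset over expressed genes 1079 were called, 558 higher and 521 lower.

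At day 7 of tamoxifen, some cell cycle, heme, oxidative phosphorylation and cholesterol synthesis genes fell in MEP cells and some megakaryocyte and interferon-stimulated genes rose. None of these lists passed camera with an estimated correlation. Cdc20, an activator of the anaphase-promoting complex, fell from 412 ± 63.1 to 15.9 ± 8.28 CPM, and Fth1, the ferritin heavy chain gene, from 2410 ± 1140 to 51.3 ± 13.9 (SD, n = 3 each). Fth1 has near-identical processed pseudogenes, so its counts are uncertain. Tfrc fell to 282 ± 55.7 CPM. Pf4 (chromosome 5, 90772435 to 90773383, plus strand), the platelet factor 4 gene, rose from 7.54 ± 5.57 to 83.6 ± 33.9 CPM, and Itga2b, the platelet integrin alpha IIb, from 15 ± 9.76 to 120 ± 46.9. Among the largest falls were those of Fth1 (-5.55 ± 0.4, SE), Podxl (-4.89 ± 0.35), Cdc20 (-4.69 ± 0.36), Thop1 (-4.56 ± 0.33), Atp5d (-4.53 ± 0.34) and Lmna (-4.51 ± 0.33). The largest rises were those of Gpc4 (4.71 ± 1.02), Sdpr (3.82 ± 0.48), Plek (3.74 ± 0.7), H2-Ob (3.71 ± 0.55), Csrp3 (3.69 ± 0.34), Fut7 (3.59 ± 0.69), Prss50 (3.57 ± 0.77) and Pf4 (3.47 ± 0.64). Each of these rises and falls had an edgeR adjusted p of at most 0.00303.

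Among the falling lists at day 7 in MEP cells, 22 of 35 mitosis genes were lower and 0 higher, for example Ccnb2 (-2.6 ± 0.29). There were 31 adjusted over the list alone (camera adjusted p = 1.16e-23, and adjusted p = 0.185 with an estimated correlation). Of 40 DNA replication genes 13 were lower, including the ribonucleotide reductase gene Rrm2 (-2.23 ± 0.27). There were 28 adjusted over the list alone (camera adjusted p = 2.71e-14, and adjusted p = 0.185 with an estimated correlation). Heme synthesis and iron uptake genes were lower in 13 of 29 cases, led by Fth1 and Tfrc (-3.21 ± 0.31). They were lower in 17 adjusted over the list alone (camera adjusted p = 6.48e-16, and adjusted p = 0.175 with an estimated correlation). Of 41 erythroid genes 12 were lower, including Rhag (-1.84 ± 0.26) and the erythropoietin receptor gene Epor (-1.92 ± 0.36), and 1, Cd36, was higher. These counts were 19 and 1 adjusted over the list alone (camera adjusted p = 5.17e-09, and adjusted p = 0.286 with an estimated correlation). Over expressed genes alone the erythroid list did not pass (camera adjusted p = 0.159). Oxidative phosphorylation genes were lower in 13 of 32 cases, led by Atp5d, and in 25 adjusted over the list alone (camera adjusted p = 1.69e-17, and adjusted p = 0.185 with an estimated correlation). Cholesterol genes were lower in 11 of 25 cases and 17 adjusted over the list alone (camera adjusted p = 2.01e-09, and adjusted p = 0.185 with an estimated correlation). Integrated stress response genes were lower in 10 of 24 cases, among them the amino acid transporter gene Slc3a2 (-3.22 ± 0.26) and Atf4 (-1.39 ± 0.25). They were lower in 15 adjusted over the list alone (camera adjusted p = 4.12e-10, and adjusted p = 0.175 with an estimated correlation). Of 24 p53 targets 8 were lower, including Bax (-2.62 ± 0.27) and Mdm2 (-2.32 ± 0.3). There were 9 adjusted over the list alone (camera adjusted p = 4.47e-07, and adjusted p = 0.273 with an estimated correlation). Over all 25274 genes tested 1778 were lower, 1663 of them among the 8161 expressed genes. The median log2 change was 0.21 over all genes and -0.38 over the expressed genes in the same fit. Camera compares a list with all other genes tested, so these ranks do not by themselves set the lists apart from other expressed genes.

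Among the rising lists at day 7 in MEP cells, 14 of 38 megakaryocyte and platelet genes were higher and 1 lower, with Itga2b at 3.01 ± 0.41 and Meis1 at 2.54 ± 0.4. Adjusted over the list alone 19 were higher and 1 lower (camera adjusted p = 1.81e-09, and adjusted p = 0.185 with an estimated correlation). Stem cell genes, which share Meis1 with that list, were higher in 11 of 37 cases, among them Gimap6 (2.41 ± 0.36). They were higher in 13 with 1 lower adjusted over the list alone (camera adjusted p = 3.89e-08, and adjusted p = 0.175 with an estimated correlation). Interferon-stimulated genes were higher in 19 of 44 cases, including Ifi44 (2.57 ± 0.41), Rtp4 (3.06 ± 0.54) and Irf7 (1.83 ± 0.3). They were higher in 25 with 1 lower adjusted over the list alone (camera adjusted p = 3.24e-12, and adjusted p = 0.185 with an estimated correlation). Of 31 STAT5 targets 7 were lower, among them Cish (-3.85 ± 0.47), Osm (-2.03 ± 0.28) and Podxl, and Serpina3g was higher. These counts were 11 and 2 adjusted over the list alone (camera adjusted p = 0.000168, and adjusted p = 0.185 with an estimated correlation). Socs2 (-0.69 ± 0.32), Pim1 (-0.37 ± 0.55), Bcl2l1 (-0.38 ± 0.24), Id1 (-2.65 ± 0.91), Socs3 (-0.45 ± 0.9) and Myc (0.1 ± 0.29) did not pass. Markers of other cell types were higher as well at low levels: 8 of 28 granulocyte and monocyte progenitor genes, over all genes and adjusted over the list alone (camera adjusted p = 1.78e-07, and adjusted p = 0.185 with an estimated correlation). Among them Lyz2 went from 3.2 ± 0.993 to 25.8 ± 3.01 CPM. S100a8 (5.4 ± 0.75) and the immunoglobulin gene Igkc (6.09 ± 0.87), which averaged 28.3 ± 13.2 CPM at day 7, also rose. Under vehicle most genes of the megakaryocyte, stem cell and granulocyte progenitor lists were lower in MEP than in LSK cells. Whether the make-up of the sorted MEP cells changed was not tested in any comparison.

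edgeR's quasi-likelihood test called 2128 of 25274 genes at day 7 in MEP cells, 350 higher and 1778 lower. Of 8161 expressed genes tested alone it called 2798, 1237 higher and 1561 lower, and with the GC offset 1365 higher and 1812 lower. The median log2 change over all genes tested was 0.21, and that of the expressed genes in the same fit was -0.38. DESeq2 called 939 higher and 2152 lower. Without tamoxifen replicate 2 the count was 1313. That library had 11.2 M counts and a TMM factor of 1.92, those of the other day 7 libraries were 1.38 and 1.24, and vehicle libraries lay between 0.94 and 1.18. Odorant and pheromone receptor genes took 0.125% ± 0.0578 of counts at day 7 and 0.052% ± 0.0143 under vehicle (SD, n = 3 each). Genes of the falling groups also varied among LSK libraries of the same treatment: at day 7 Pfn1 spanned 14.2 to 587 CPM and Atp5d 17.4 to 234 CPM over the 4 LSK libraries.

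Between day 3 and day 7 of tamoxifen in MEP cells, some megakaryocyte genes rose and some mitosis and heme genes fell. Pf4 rose by 4.18 ± 0.59 (SE), Plek by 5.08 ± 0.66, Fut7 by 3.98 ± 0.63, the antigen presentation gene Cd74 by 4.24 ± 0.58 and Ctla2a by 4.41 ± 0.46. Fth1 fell by 5.52 ± 0.39 (edgeR adjusted p = 5.16e-10). Mrps34 (-9.28 ± 1.79), Pfn1 (-5.9 ± 0.62), Phb2 (-5.09 ± 0.47) and Bsg (-4.93 ± 0.39) fell as well. Pfn1, Phb2 and Bsg had shifts of 2.66, 1.64 and 1.59 between vehicle libraries of the same animal number, and Mrps34 was higher by 4.01 ± 1.03 in MEP vehicle libraries of batch C than of batch A. Of 38 megakaryocyte and platelet genes 17 rose, and 19 with 1 lower adjusted over the list alone (camera adjusted p = 2.83e-11, and adjusted p = 0.287 with an estimated correlation). Of 35 mitosis genes 13 fell, and 31 adjusted over the list alone (camera adjusted p = 1.73e-15, and adjusted p = 0.287 with an estimated correlation). Of 29 heme synthesis and iron uptake genes 9 fell, and 16 adjusted over the list alone (camera adjusted p = 3.61e-13, and adjusted p = 0.287 with an estimated correlation). Cish differed by 1.38 ± 0.44, which did not pass (edgeR adjusted p = 0.0607). edgeR called 1887 genes, 263 higher and 1624 lower. The splits were 674 higher and 1383 lower over expressed genes alone, 727 and 1856 in DESeq2, 1029 and 1442 with the GC offset, and 72 and 593 with the factor from the vehicle pairs. The median over all genes was 0.18, and over the expressed genes in the same fit -0.33. Of the 8161 expressed genes 1485 were lower in that fit, and the camera ranks of this comparison are taken against all genes.

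Under ruxolitinib, which addresses inhibition of the kinase in place of its deletion, some STAT5 targets and interferon-stimulated genes fell in MEP cells and some megakaryocyte genes rose, while other STAT5 targets and megakaryocyte genes moved the opposite way. Cish fell by 3.22 ± 0.45 (SE; edgeR adjusted p = 7.28e-05), Socs2 by 2.15 ± 0.34 (edgeR adjusted p = 0.000134), Pim1 by 1.86 ± 0.57 and Osm by 0.96 ± 0.27 (edgeR adjusted p = 0.00779). Pim1 was low, at 1.59 to 3.6 CPM under vehicle and 0.312 to 1.06 under ruxolitinib. The median over all genes tested was -1.07, so the fall of Pim1 is not separated from the falls among low genes. Itga2b rose from 11.5 ± 7.15 to 136 ± 25.8 CPM and Pf4 from 7.07 ± 7.88 to 72.7 ± 29.1 (SD, n = 3 each). Meis1 rose by 3.04 ± 0.41. Irf7 fell from 32.7 ± 8.19 to 6.65 ± 1.05 CPM, Rtp4 from 7.03 ± 3.64 to 0.407 ± 0.295, and the interferon-induced protease gene Usp18 by 2.33 ± 0.31. Tfrc fell from 2490 ± 791 to 802 ± 113 CPM. Genes of granulocyte progenitors rose too: Mpo, the myeloperoxidase gene, from 2.57 ± 1.65 to 79.6 ± 51 CPM, and Lyz2 from 1.98 ± 1.45 to 33.1 ± 12.5. The other largest rises were those of Apoe (4.55 ± 0.68, with a shift of 2.61 between vehicle batches), Ifitm1 (4.49 ± 0.55), Cd34 (4.49 ± 0.58), Cpa3 (4.3 ± 0.59), Eltd1 (4.29 ± 0.61) and Rnf17 (4.06 ± 0.44). Among the largest falls were those of Chgb (-6.07 ± 0.78; 2.32 ± 1.43 to 0.0283 ± 0.0491 CPM), Fam198b (-5.46 ± 0.72) and Plk2 (-6.24 ± 1.16), whose vehicle libraries spanned 2.08 to 74.1 CPM.

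By list under ruxolitinib in MEP cells, 12 of 31 STAT5 targets were lower and 4 higher, over all genes and adjusted over the list alone. Of all 25274 genes tested 9737 were lower, a similar share, so the count of 12 does not set these targets apart. Their median log2 change was -0.39, while camera ranked the list upward without passing (adjusted p = 0.431, and adjusted p = 0.716 with an estimated correlation). Bcl2l1 (0.38 ± 0.24), Id1 (-1.92 ± 0.88), Socs3 (1.04 ± 0.83) and Myc (0.5 ± 0.29) did not pass. Interferon-stimulated genes were lower in 21 of 44 cases, and in 23 adjusted over the list alone (camera adjusted p = 0.0307, and adjusted p = 0.68 with an estimated correlation). Over expressed genes alone 13 of 30 were lower (camera adjusted p = 6e-12, and adjusted p = 0.186 with an estimated correlation). Megakaryocyte and platelet genes were higher in 17 of 38 cases and lower in 5, with 17 and 6 adjusted over the list alone (camera adjusted p = 1.12e-13, and adjusted p = 0.194 with an estimated correlation). Stem cell genes were higher in 12 of 37 cases and lower in 4, over all genes and adjusted over the list alone (camera adjusted p = 2.01e-10, and adjusted p = 0.17 with an estimated correlation). Granulocyte and monocyte progenitor genes were higher in 11 of 28 cases and lower in 4, in both countings (camera adjusted p = 1.81e-09, and adjusted p = 0.303 with an estimated correlation). Mitosis genes had 3 of 35 members lower, Mki67 (-1.19 ± 0.25), Cenpf (-0.74 ± 0.23) and Cenpe, and 1 adjusted over the list alone. Camera ranked that list upward over all genes (adjusted p = 0.0259, and adjusted p = 0.711 with an estimated correlation) and downward over expressed genes (adjusted p = 0.0138, and adjusted p = 0.646 with an estimated correlation). Its median log2 change was 0 and its mean -0.1. Camera compares a list with all other genes tested. The median over all genes was -1.07 in this comparison and that over expressed genes in the same fit 0.11. An upward rank over all genes therefore does not by itself mean that a list rose.

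Under ruxolitinib in MEP cells, edgeR's quasi-likelihood test called 10605 of 25274 genes, 868 higher and 9737 lower, with a median log2 change over all genes of -1.07 and over the expressed genes in the same fit of 0.11. Tested alone, 1123 of 8161 expressed genes were called, 341 higher and 782 lower, and with the GC offset 391 higher and 876 lower. With the factor from the vehicle pairs 112 were higher and 323 lower. In the tests over all and over expressed genes, 834 genes were called in the same direction. Odorant and pheromone receptor genes, which blood progenitors do not use, took 0.0028% ± 0.00145 of counts under ruxolitinib and 0.021% ± 0.0115 under vehicle (SD, n = 3 each). The count was 7068 without vehicle replicate 2. With the libraries of both compared groups alone in the fit it was 3090.

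**Figure D2:**
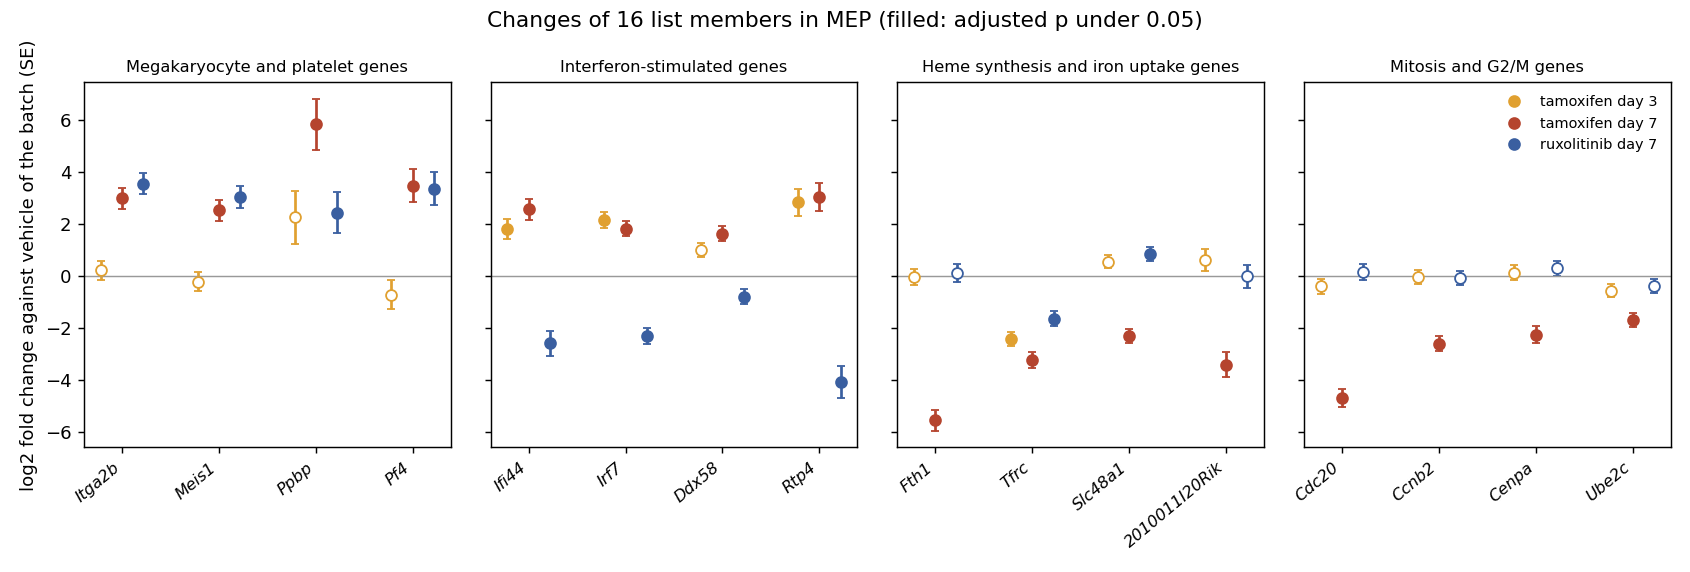
Log2 fold changes in MEP cells with their SE for 16 genes, the 4 with the smallest p at tamoxifen day 7 in each of 4 lists, at tamoxifen day 3 (yellow), day 7 (red) and under ruxolitinib (blue), each against vehicle of its batch; filled points have an adjusted p under 0.05. Itga2b lies at 3.01 at day 7 and 3.56 under ruxolitinib, whereas Irf7 lies at 1.83 at day 7 and -2.3 under ruxolitinib.

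The day 7 response to tamoxifen and the response to ruxolitinib were then compared with each other in MEP cells, each taken against vehicle of its own batch. Interferon-stimulated genes separated them: the difference was 7.13 ± 0.83 (SE) for Rtp4 (edgeR adjusted p = 1.97e-06), 5.15 ± 0.63 for Ifi44 and 4.13 ± 0.43 for Irf7 (edgeR adjusted p = 5.69e-07), all higher after tamoxifen. Of 44 such genes 30 were higher after tamoxifen and 0 lower, over all genes and adjusted over the list alone (camera adjusted p = 7.13e-07, and adjusted p = 0.466 with an estimated correlation). Fth1 (-5.67 ± 0.5) and Cdc20 (-4.84 ± 0.46) were lower after tamoxifen. So were 19 of 35 mitosis genes, and 20 adjusted over the list alone (camera adjusted p = 6.58e-13, and adjusted p = 0.466 with an estimated correlation). Lower too were 25 of 32 oxidative phosphorylation genes, and 26 adjusted over the list alone (camera adjusted p = 2.77e-18, and adjusted p = 0.463 with an estimated correlation). Socs2 was higher by 1.46 ± 0.46 and Osm lower by -1.08 ± 0.39 after tamoxifen. Among the largest differences were those of Rps4y2 (7.24 ± 2.19), Rtp4, Chgb (6.86 ± 0.95), Ptk6 (5.42 ± 0.83) and Myh4 (5.29 ± 0.81) upward, and of Mrps34 (-7.95 ± 2.39, beside 4.01 ± 1.03 between the MEP vehicle batches), Fth1, Thop1 (-5.54 ± 0.43) and Zfp574 (-5.08 ± 0.43) downward. edgeR called 11620 genes, 9229 higher and 2391 lower after tamoxifen. The splits were 1295 and 1287 over expressed genes alone, 1392 and 1513 with the GC offset, and 275 and 387 with the factor from the vehicle pairs. The median over all genes was 1.38, and over the expressed genes in the same fit -0.49. The camera ranks given here are taken against all genes.

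In LSK cells at day 3 of tamoxifen, no gene passed edgeR's quasi-likelihood test. The count was 0 of 26930, with 1019 genes at an unadjusted p under 0.05. DESeq2 called 93, 16 higher and 77 lower, and limma voom 56. Cish (-2.01 ± 0.43, SE) and Socs2 (-1.08 ± 0.27) had edgeR adjusted p of 0.212 and 0.394. Osm (-0.25 ± 0.3), Pim1 (-0.75 ± 0.52), Bcl2l1 (-0.54 ± 0.23), Id1 (-2.08 ± 0.6), Socs3 (-2.72 ± 1.16) and Myc (-0.36 ± 0.49) did not pass either. As lists, STAT5 targets ranked downward with a median of -0.68 and 9 of 31 lower adjusted over the list alone, 0 over all genes (camera adjusted p = 4.19e-14, and adjusted p = 0.0726 with an estimated correlation). Lymphoid priming genes, which mark the first steps towards lymphocytes, ranked downward with 8 of 22 lower adjusted over the list alone and 0 over all genes (camera adjusted p = 2.21e-09, and adjusted p = 0.000801 with an estimated correlation). B cell genes ranked downward too, with 3 of 19 lower adjusted over the list alone and 0 over all genes (camera adjusted p = 0.00777, and adjusted p = 0.403 with an estimated correlation). Igj (-6.58 ± 1.34) and Igkc (-5.17 ± 1.34) did not pass, and the vehicle libraries spanned 93.8 to 3570 and 150 to 7340 CPM for them. Macrophage genes ranked upward with a median of 1.78 and 0 of 18 called in either counting (camera adjusted p = 1.33e-23, and adjusted p = 0.0924 with an estimated correlation). C1qa averaged 192 ± 157 CPM at day 3 and 44.5 ± 74.5 under vehicle (SD, n = 3 and 4). The mean log2 CPM of the macrophage list was 7.35 in vehicle replicate 3 and at most 3.87 in the other vehicle libraries. Without vehicle replicate 3 the count of calls was 88. It was 3, 2 and 1 without vehicle replicates 1, 2 and 4 and 1 without tamoxifen replicate 1.

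At day 7 of tamoxifen, some granulocyte progenitor genes rose in LSK cells, and some STAT5 targets and red cell genes fell. Elane (chromosome 10, 79886247 to 79888215, plus strand) rose from 264 ± 138 to 1570 ± 593 CPM, the coagulation factor gene F13a1 from 36.3 ± 22.6 to 307 ± 151, and S100a8, a calgranulin of neutrophils, from 1.33 ± 0.604 to 45.8 ± 19.3 (SD, n = 4 each). The log2 changes were 2.58 ± 0.47 (SE; edgeR adjusted p = 0.0388), 3.08 ± 0.49 (edgeR adjusted p = 0.0219) and 5.1 ± 0.49 (edgeR adjusted p = 0.000134). S100a9 (4.36 ± 0.71), Trem3 (2.93 ± 0.5), Gzmb (2.34 ± 0.36), Igsf6 (2.18 ± 0.35) and Ms4a3 (2.14 ± 0.38) rose too. Socs2 fell by 1.68 ± 0.25 (edgeR adjusted p = 0.0219), Serpina3f by 2.97 ± 0.43, Gadd45g by 1.45 ± 0.27 and Tfrc by 1.89 ± 0.33. Among other genes Slc4a1 fell by 3.61 ± 0.63, Mycn by 3.07 ± 0.57, Plxdc2 by 1.7 ± 0.31 and the interferon-inducible GTPase genes Gbp4 and Gbp6 by 2.59 ± 0.41 and 2.63 ± 0.45. Cish (-1.61 ± 0.38) did not pass (edgeR adjusted p = 0.116), nor did Osm (-0.79 ± 0.28), Pim1 (-0.49 ± 0.47), Bcl2l1 (-0.52 ± 0.21), Id1 (-1.79 ± 0.53), Socs3 (-4.71 ± 1.16) or Myc (-0.37 ± 0.45).

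By list at day 7 in LSK cells, 6 of 30 granulocyte and monocyte progenitor genes rose and 0 fell, and 14 rose and 2 fell adjusted over the list alone (camera adjusted p = 8.51e-24, and adjusted p = 0.0509 with an estimated correlation). Mature neutrophil genes rose in 3 of 20 cases and 8 adjusted over the list alone (camera adjusted p = 7.43e-16, and adjusted p = 0.0509 with an estimated correlation). Of 31 STAT5 targets 3 fell, and 13 adjusted over the list alone (camera adjusted p = 2.37e-14, and adjusted p = 0.0509 with an estimated correlation). Of 41 erythroid genes Tfrc and Slc4a1 fell, and 10 adjusted over the list alone (camera adjusted p = 5.1e-11, and adjusted p = 0.191 with an estimated correlation). Macrophage genes had a median of -2.16 and 10 of 18 lower adjusted over the list alone, 0 over all genes (camera adjusted p = 0.00151, and adjusted p = 0.473 with an estimated correlation). edgeR's quasi-likelihood test called 28 of 26930 genes, 15 higher and 13 lower, against 56 and 270 in DESeq2. That count moved to 2, 5, 4 or 911 without tamoxifen replicate 1, 2, 3 or 4, and to 73, 53, 10 or 7 without vehicle replicate 1, 2, 3 or 4. The 911 were 48 higher and 863 lower. In the plot of set medians by LSK library, the granulocyte list lay above the vehicle mean in each day 7 library, in each day 3 library (0.43, 0.93 and 0.7) and in vehicle replicate 2 (0.58) and 4 (0.04).

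**Figure D3:**
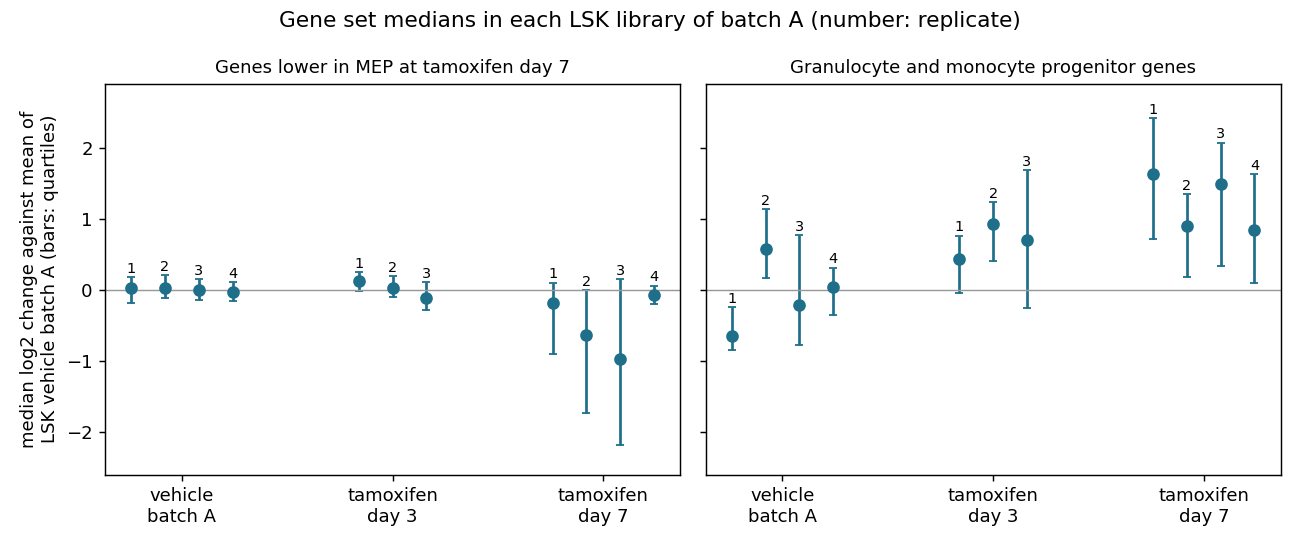
Median log2 change against the mean of the 4 LSK vehicle libraries of batch A, with quartiles as bars, for each LSK library of batch A (numbers are replicates): expressed genes lower in MEP cells at tamoxifen day 7 on the left, granulocyte and monocyte progenitor genes on the right. The day 7 medians are -0.19, -0.64, -0.98 and -0.07 on the left and 1.63, 0.9, 1.49 and 0.84 on the right.

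Under ruxolitinib in LSK cells, a few genes fell, among them interferon-stimulated ones. Slfn2, an interferon-inducible growth regulator, fell from 64.2 ± 2.55 CPM (SD, n = 2) to 8.5 ± 1.33 (n = 3), a log2 change of -2.92 ± 0.34 (SE; edgeR adjusted p = 0.00118). Irf7 fell from 91.7 ± 62.8 to 17.4 ± 2.51 CPM, Rtp4 from 83.1 ± 40.1 to 14.2 ± 2.75 and Serpina3f from 65.2 ± 19.5 to 6.07 ± 1.95. Plscr2 rose from 8.17 ± 2.7 to 94.3 ± 4.15. The sixth gene called, the unnamed transcript 3830403N18Rik (9.92 ± 0.81), lies outside the naming rule and was chosen after its values were seen. It was near absent in all libraries without ruxolitinib, so a difference of animals beside the drug is not excluded. Socs2 (-1.07 ± 0.31), Cish (-1.32 ± 0.47), Osm (-0.55 ± 0.35), Pim1 (-2.14 ± 0.6), Bcl2l1 (-0.05 ± 0.27), Id1 (-2.23 ± 0.67), Socs3 (-3.26 ± 1.26) and Myc (-0.83 ± 0.58) did not pass. Of 46 interferon-stimulated genes Irf7 and Rtp4 fell, and 17 adjusted over the list alone (camera adjusted p = 1.65e-11, and adjusted p = 0.529 with an estimated correlation). Over 39 expressed members the camera adjusted p was 7.3e-42, and 0.00193 with an estimated correlation. STAT5 targets had 1 of 31 lower, and 7 adjusted over the list alone (camera adjusted p = 0.000862, and adjusted p = 0.529 with an estimated correlation). DNA replication genes ranked upward with a median of 0.44 and 0 of 40 called in either counting (camera adjusted p = 1.65e-11, and adjusted p = 0.529 with an estimated correlation). edgeR called 6 of 26930 genes, 2 higher and 4 lower. The splits were 4 and 4 with RLE factors, 1 and 8 over expressed genes alone, 1 and 9 with the GC offset, and 62 and 78 in DESeq2. The median over all genes was -0.25. The count was 4, 4 and 3 without ruxolitinib replicates 1, 2 and 3, and 2 of the 6 genes kept their call each time.

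Between day 3 and day 7 in LSK cells, edgeR called mt-Rnr1, a mitochondrial ribosomal RNA gene, higher (2.69 ± 0.3, SE) and Il18bp, which encodes a decoy of interleukin 18, lower (-2.85 ± 0.36). Erythroid genes ranked downward with 25 of 41 lower adjusted over the list alone and 0 over all genes (camera adjusted p = 8.97e-21, and adjusted p = 0.0619 with an estimated correlation). Macrophage genes ranked downward too, with a median of -3.94 and 16 of 18 lower adjusted over the list alone, 0 over all genes (camera adjusted p = 6.6e-26, and adjusted p = 0.0619 with an estimated correlation). Over expressed genes alone 30 were higher and 222 lower, in DESeq2 37 and 249, and with the GC offset 34 and 245. The count of 2 became 4 and 1 without day 3 replicates 2 and 3, and 797 without day 7 replicate 4. For the LSK response to tamoxifen at day 7 less that to ruxolitinib, edgeR called 1 gene, the unnamed transcript 3830403N18Rik, chosen after its value was seen and lower after tamoxifen (-10.38 ± 0.94). The splits were 4 higher and 1 lower over expressed genes alone, 2 and 1 with the GC offset, and 11 and 13 in DESeq2. There the interferon list ranked higher after tamoxifen, with 7 of 46 higher adjusted over the list alone and 0 over all genes (camera adjusted p = 1.07e-06, and adjusted p = 0.362 with an estimated correlation). The median over all genes was 0.12. The count was 322 without tamoxifen replicate 4, and 2 without tamoxifen replicate 3, ruxolitinib replicate 1, or vehicle replicate 1 or 2 of batch C.

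Whether MEP and LSK cells responded differently was tested as the difference of their responses. Some LSK and MEP libraries of a treatment carry the same animal number, and the fit treats them as independent. Deviations from group means of such libraries correlated between the cell types at -0.26 to 0.31. At day 3 the fall was deeper in MEP cells for Gab2 (-4.44 ± 0.69, SE), B3gnt7 (-4.18 ± 0.69), Podxl (-3.6 ± 0.45), Cda (-3.57 ± 0.49), Fam124a (-3.39 ± 0.64) and Cish (-3.19 ± 0.6; edgeR adjusted p = 0.0198). By contrast Armcx2 (2.07 ± 0.39), Ly6a (6.35 ± 1.11) and Igj (7.02 ± 1.38) moved upward relative to LSK cells. In LSK cells themselves Ly6a (-2.08 ± 0.45) and Igj (-6.58 ± 1.34) had changes that did not pass. Ly6a was also far lower in MEP than in LSK cells under vehicle. The differences for Ly6a and Igj therefore need not be rises in MEP cells. At day 7 the upward differences included Serpina3f (4.39 ± 0.66), Itga2b (3.13 ± 0.51) and Irf7 (2.01 ± 0.47). The downward ones included Cdc20 (-3.7 ± 0.76), Fabp5 (-3.61 ± 0.41), Podxl (-3.55 ± 0.46) and Fth1 (-3.53 ± 0.85). The rise of megakaryocyte and platelet genes was greater in MEP cells, with 9 of 39 higher and 20 adjusted over the list alone at day 7 (camera adjusted p = 4.06e-22, and adjusted p = 0.00999 with an estimated correlation). Under ruxolitinib 4 of 39 were higher, and 13 with 2 lower adjusted over the list alone (camera adjusted p = 1.4e-21, and adjusted p = 0.00913 with an estimated correlation), including Itga2b (3.45 ± 0.57), Meis1 (2.76 ± 0.59) and Plek (3.91 ± 0.84). Mpo (4.58 ± 0.83), Cd34 (4.43 ± 0.81), Ifitm1 (4.69 ± 0.96), Eltd1 (4.56 ± 0.74) and Fut7 (4.16 ± 0.93) also had upward differences under ruxolitinib. Those of Cma1 (-6.44 ± 1.32), Fam198b (-4.78 ± 0.93), Evc (-4.26 ± 0.79), Klf12 (-4.14 ± 0.96) and Ppp1r16b (-3.82 ± 0.7) were downward. Interferon-stimulated genes were higher relative to LSK cells in 5 of 46 cases at day 7, and in 18 adjusted over the list alone (camera adjusted p = 2.62e-15, and adjusted p = 0.0772 with an estimated correlation). Mitosis genes were lower in 6 of 35 cases at day 7, and in 32 adjusted over the list alone (camera adjusted p = 4.01e-34, and adjusted p = 0.054 with an estimated correlation).

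Over 28378 genes, edgeR's quasi-likelihood test of these differences called 15 at day 3, 6 higher and 9 lower in MEP cells. It called 130 at day 7, 84 higher and 46 lower, and 83 under ruxolitinib, 35 higher and 48 lower. Over expressed genes alone the splits were 12 and 15, 550 and 505, and 37 and 23. With the GC offset they were 664 and 722 at day 7 and 43 and 29 under ruxolitinib. DESeq2 gave 48 and 23 at day 3 and 110 and 510 under ruxolitinib. The medians over all genes were 0.22 at day 7 and -0.59 under ruxolitinib. Those over expressed genes in the same fit were -0.31 and 0.07, and the camera ranks above are taken against all genes. At day 3 the count was 8 without LSK tamoxifen replicate 3, 24 and 54 without LSK vehicle replicates 1 and 3, 7 without MEP tamoxifen replicate 3, and 9, 6 and 9 without MEP vehicle replicates 1, 2 and 3. At day 7 it was 48 and 264 without LSK tamoxifen replicates 1 and 3, 275 without LSK vehicle replicate 2, 78, 56 and 33 without MEP tamoxifen replicates 1, 2 and 3, and 29 and 47 without MEP vehicle replicates 2 and 3. Under ruxolitinib it was 1047, 32 and 8 without LSK ruxolitinib replicates 1, 2 and 3, 600 and 0 without LSK vehicle replicates 1 and 2, 163 and 26 without MEP ruxolitinib replicates 1 and 3, and 32 and 250 without MEP vehicle replicates 2 and 3.

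Vehicle libraries of batch C and batch A differed with no treatment between them. In LSK cells the largest differences, higher in batch C, were those of Rbm38 (4.37 ± 0.64, SE), Zfp358 (4.21 ± 0.78), Fbxl6 (4.11 ± 0.61), Tbcc (3.99 ± 0.7) and Pkmyt1 (3.85 ± 0.64). In MEP cells Serp1 (4.14 ± 0.91), Mrps34 (4.01 ± 1.03), Tsnax (3.97 ± 0.76), Hist1h2ae (3.64 ± 0.91) and H2afx (3.63 ± 0.86) were higher and Tnip3 (-2.06 ± 0.43), Robo2 (-2.02 ± 0.46), Acvr1c (-1.99 ± 0.54) and Vcan (-1.98 ± 0.45) lower. Oxidative phosphorylation genes were higher in batch C in 2 of 32 cases in LSK cells and 3 adjusted over the list alone (camera adjusted p = 2.28e-12, and adjusted p = 0.565 with an estimated correlation). In MEP cells 3 of 32 were higher, over all genes and adjusted over the list alone (camera adjusted p = 5.59e-08, and adjusted p = 0.624 with an estimated correlation). edgeR called 208 genes in LSK cells, 196 higher and 12 lower, and 889 in MEP cells, 695 higher and 194 lower. DESeq2 gave 447 and 335, and 1397 and 2341. The MEP split over expressed genes alone was 90 and 46, with 186 and 96 under the GC offset. The medians over all genes were -0.23 and -0.27. With the animal number as a block over the vehicle libraries alone, LSK calls numbered 783. The LSK count became 5, 740, 5 and 2 without batch A replicates 1 to 4 and 529 and 0 without batch C replicates 1 and 2. The MEP count became 21 without batch A replicate 3 and 1425 and 413 without batch C replicates 2 and 3.

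Sharing of calls was counted between comparisons. In MEP cells 48 genes were higher and 65 lower at both day 3 and day 7, against 3.1 and 5.8 for independent lists. The 113 in all became 71 and 69 without vehicle replicates 2 and 3. Of the genes higher at day 3, 58 were lower at day 7, against 15.8, but over expressed genes alone 90 were, against 102.1. Across genes, which are not independent replicates, the log2 changes of the 2 times had Pearson's r of 0.32, below the 0.54 of simulated unchanged groups with the same vehicle libraries, and a covariance of 0.159 beside the simulated 0.163. Over expressed genes the covariance was 0.083 beside 0.035. With the vehicle libraries divided, 1 for a day and 2 for the other in 6 ways, the mean r was 0.09 and the mean covariance 0.103, or 0.043 over expressed genes. On average 6.3 higher and 28.2 lower genes were then shared, in tests with fewer vehicle libraries. In LSK cells the observed r was 0.55, the simulated 0.46, and the mean over 6 splits of the vehicle libraries -0.02, with covariances of 0.293, 0.181 and -0.016. Day 7 of tamoxifen and ruxolitinib have separate vehicle libraries that carry the same animal numbers, which the numbers for independent lists leave out of account. They shared 156 higher genes in MEP cells, against 12 for independent lists, and 99 lower ones, against 685. Over expressed genes alone they shared 134 higher, against 51.7, and 85 lower, against 149.6. That total of 219 became 68 with the factor from the vehicle pairs. Over expressed genes 199 genes higher at day 7 were lower under ruxolitinib, against 118.5, and 60 lower ones were higher, against 65.2. Over all genes these counts were 33, against 134.8, and 135, against 61.1. Pearson's r of the log2 changes was -0.04 over expressed genes and -0.35 over all genes.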

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

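The 7 tests of the patterns below, on library medians, GC content, receptor genes, scaling, neutrophil genes and ruxolitinib, were chosen only after the result was seen; the counts of other splits of the samples were planned, except that for the ruxolitinib responses of MEP and LSK cells.

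Among the 3 groups with 4 libraries, 84 measures were searched for a library far from the rest, of which 7 stood out where chance gives about 4.2. In LSK vehicle A replicate 2, the total of 28838622 counts (28.8 M) stood above the next at 15.3 M, the TMM factor of 0.8 below the next at 1.2, and Socs3 at 53.5 CPM above the next at 5.48. In LSK vehicle A replicate 3, Id1 was lowest at 2.47 CPM with the next at 7.26, and macrophage genes had the highest mean log2 CPM, 7.35 with the next at 3.87. Pim1 was highest in LSK tamoxifen day 7 replicate 3, at 7.18 CPM with the next at 5.78. In MEP tamoxifen day 3 replicate 1, the mean log2 CPM of mast cell, basophil and eosinophil genes was lowest, at -0.26 with the next at 0.23.

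Effects that differed between groups by a test of the difference itself were the responses of MEP and LSK cells and those of the days of tamoxifen. The response to tamoxifen at day 3 differed between MEP and LSK cells for 15 genes, among them Cish at -3.19 on the log2 scale. Of 100 splits of the libraries 7 called as many, with up to 64. At day 7 it differed for 130 genes, and 10 of 100 splits called as many, with up to 886. Under ruxolitinib 83 genes differed between MEP and LSK cells, and 17 of 100 splits called as many, with up to 9101. These splits regrouped the libraries of each cell type separately. A split near the real grouping in 1 cell type alone can turn the response of that cell type into a difference. The splits therefore do not test for equal responses, and chance is not excluded for any of these counts. Day 7 and day 3 of tamoxifen differed for 1887 genes in MEP cells. There 1 of 35 splits, the real one, called as many and the highest other called 205. This argues against chance, at a threshold not adjusted for the number of comparisons. In LSK cells day 7 and day 3 differed for 2 genes, and 2 of 35 splits called as many. The highest called 781, with day 7 replicate 4 grouped with the day 3 libraries, which points to a structure of the samples.

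Genes lower in MEP cells at day 7 of tamoxifen formed a pattern of 1561 expressed genes. A GC trend is argued against as the whole cause, since 98.3% of them stayed called lower with the GC offset. Loss of JAK2 signalling shared with ruxolitinib is argued against too, as their median log2 change under ruxolitinib was 0.07, with quartiles of -0.14 and 0.27. A difference between libraries that is not treatment stays open, because the median of these genes ranged by 0.91 among the LSK day 7 libraries, from -0.07 to -0.98, while LSK vehicle libraries lay between -0.03 and 0.03. An effect of tamoxifen or of the deletion that ruxolitinib does not have also stays open, untested, and 10 splits of the samples are too few for a share under 0.05, with 2128 genes called by the real one and 1 by the highest other.

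Genes lower in MEP cells under ruxolitinib numbered 9737 over all genes and 782 over expressed genes alone. A single scaling factor for these libraries is argued against, since the median of expressed genes lay 3.17 above that of odorant and pheromone receptor genes. Fewer background counts over silent genes may account for the falls among low genes: the 646 receptor genes tested had a median of -3.06, with 328 lower and 0 higher. Splits of the samples numbered 10, too few for a share under 0.05, with 10605 genes called by the real one and 2048 by the highest other. A biological cause of the falls among low genes was not tested.

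Some granulocyte progenitor genes were higher in LSK cells at day 7 of tamoxifen. Mature neutrophils in the sort are argued against for the progenitor genes, because the gain of Elane was at least 8.13 times that of S100a8 and S100a9 together in each day 7 library. A difference among libraries stays open, as the lowest median of the list at day 7 was 0.84, close to the vehicle range of -0.65 to 0.58 and within the day 3 range of 0.43 to 0.93. A shift of the gate towards granulocyte progenitors, and a change of the LSK cells themselves after deletion, stay open and were not tested. Over all genes 28 were called, 2 of 35 splits called as many, and 468 were called when day 7 replicates 1, 2 and 3 were grouped with vehicle replicate 1, so chance is not excluded for that count and the samples hold some other structure.

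In the other comparisons, LSK day 3 called 0 genes in edgeR, with 1019 at an unadjusted p under 0.05, 93 in DESeq2 and 56 in limma voom. All 35 of its splits called as many, which a real count of 0 fixes in advance. The highest, vehicle replicates 1, 2 and 4 against the rest, called 98, which points to a structure of the samples. For MEP cells at day 3 the real split was alone among 35 in calling as many (306 genes, highest other 238). So it was for MEP against LSK cells under vehicle (4941, highest other 3158). This is the lowest share that 35 splits allow, and the 0.05 threshold was not adjusted for the number of comparisons. It argues against chance for these counts but does not exclude it. Leaving out each library in turn gave 98 to 383 genes for MEP day 3. For the MEP response to tamoxifen at day 7 less that to ruxolitinib, 1 of 100 splits, the real one, called as many (11620, highest other 8723). The splits regrouped the libraries of each response separately, so a response to 1 treatment alone can appear in them as a difference. They therefore do not test whether the responses are equal, and no conclusion on chance is drawn. They also take vehicle libraries of the same animal number as independent. Of 3 such pairs, 2 had deviations correlated at 0.56 and 0.53. For MEP vehicle batches 10 splits are too few for a share under 0.05, with 889 genes called by the real one and 33 by the highest other.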

How the results depend on the processing

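The tests over expressed genes alone, with the vehicle pair factor or with the GC offset, and the counts without genes shifted in all vehicle pairs of the other cell type, were chosen only after the result was seen; the others were planned. Counts of called genes are given where they moved by over 1.5 times from those in the report; where a cause is not named it was not tested. Comparisons are given as LSK or MEP with day 3, day 7 or ruxolitinib against vehicle, day 7 against day 3, the day 7 response less the ruxolitinib response, batch C against A, and the MEP less the LSK response.

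With RLE factors the MEP less LSK response at day 7 called 231 genes. DESeq2 called 93, 326 and 140 genes for LSK day 3, day 7 and ruxolitinib, 286 for LSK day 7 against day 3, 24 for LSK day 7 less ruxolitinib, 782 and 3738 for batch C against A in LSK and MEP cells, and 666 for MEP day 3. It called 71, 892 and 620 for the MEP less LSK responses at day 3, day 7 and under ruxolitinib. Without a count filter LSK day 3, day 7 and ruxolitinib gave 2, 54 and 14. LSK day 7 against day 3 gave 16, LSK day 7 less ruxolitinib 2, and the MEP less LSK ruxolitinib response 158. limma voom with the animal number as a random block, at a consensus correlation of 0.045, gave 56, 610 and 28 for LSK day 3, day 7 and ruxolitinib. It gave 579 for LSK day 7 against day 3, 60 for LSK day 7 less ruxolitinib, 438 for LSK batches, 64 for MEP day 3, and 8, 52 and 21 for the MEP less LSK responses.

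The replicate block, with replicate numbers that share only a number between treatment and vehicle, gave 230 for LSK day 7, 267 for LSK day 7 against day 3, 2 for LSK day 7 less ruxolitinib, 4 for LSK batches and 54 for the MEP less LSK ruxolitinib response. Deviations of same-numbered libraries correlated at 0.03 to 0.36 for LSK day 3, -0.13 to 0.04 for LSK day 7, and -0.31 to -0.14 for LSK ruxolitinib. For MEP day 3, day 7 and ruxolitinib they correlated at -0.14 to 0.19, -0.35 to 0.02 and -0.13 to 0.26, so the numbers were not taken as pairs. Paired by animal number over the vehicle libraries alone, LSK batches gave 783, and the MEP count stayed within 1.5 times.

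Over expressed genes alone, where fewer genes are tested, LSK day 7 gave 66, LSK day 7 against day 3 252, and LSK day 7 less ruxolitinib 5. In the same test MEP day 3 gave 773, MEP ruxolitinib 1123, MEP day 7 less ruxolitinib 2582, MEP batches 136, and the MEP less LSK responses at day 3 and day 7 27 and 1055. With the vehicle pair factor as well, LSK day 7 and ruxolitinib gave 113 and 10, LSK day 7 against day 3 499, LSK day 7 less ruxolitinib 15, and LSK and MEP batches 3 and 7. MEP day 3 and ruxolitinib then gave 570 and 435, MEP day 7 against day 3 665, MEP day 7 less ruxolitinib 662, and the MEP less LSK responses at day 7 and under ruxolitinib 911 and 48. With the GC offset LSK day 3, day 7 and ruxolitinib gave 1, 65 and 10, LSK day 7 against day 3 279, and LSK day 7 less ruxolitinib 3. MEP day 3 and ruxolitinib gave 1079 and 1267 with it, MEP day 7 less ruxolitinib 2905, MEP batches 282, and the MEP less LSK responses at day 3 and day 7 49 and 1386. Leaving out genes shifted in all vehicle pairs of the other cell type kept the counts it applied to within 1.5 times.

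With the compared groups alone in the fit, which leaves fewer samples for the spread, LSK day 3, day 7 and ruxolitinib gave 2, 9 and 11, LSK day 7 against day 3 289, and LSK and MEP batches 0 and 146. MEP day 3 and ruxolitinib gave 633 and 3090 in such fits, and the MEP less LSK responses 7, 70 and 34. For the LSK batch count of 0 in edgeR, 2063 genes had an unadjusted p under 0.05, and with all LSK libraries in the fit DESeq2 gave 782 and voom 438. Pooling vehicle batches gave 1, 55 and 5341 for LSK day 3, day 7 and ruxolitinib and 4950 for MEP day 7. Of the list tests 1 passed with an estimated correlation and 33 with fry, against 98. The 113 genes called in 1 direction at both days in MEP cells became 270 in DESeq2, 50 in voom, 394 over expressed genes, 230 with the pair factor, 633 with the GC offset, 195 with the compared groups alone and 192 with pooled vehicles. It was 69 to 79 without each vehicle library in turn. The 255 shared by MEP day 7 and ruxolitinib became 390 in DESeq2, 160 in voom, 68 with the pair factor and 387 with pooled vehicles.

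Leaving out each library in turn gave 0 to 88 genes for LSK day 3, 2 to 911 for LSK day 7, and 2 to 4 for LSK ruxolitinib. It gave 1 to 797 for LSK day 7 against day 3, 1 to 322 for LSK day 7 less ruxolitinib and 0 to 740 for LSK batches. In MEP cells the ranges were 98 to 383 for day 3, 1313 to 2093 for day 7, and 7068 to 12024 for ruxolitinib. They were 1304 to 1906 for day 7 against day 3, 8496 to 13831 for day 7 less ruxolitinib, 21 to 1425 for batches and 3622 to 5288 for MEP against LSK. The MEP less LSK responses ranged over 6 to 54 at day 3, 29 to 275 at day 7 and 0 to 1047 under ruxolitinib. Where this left 1 LSK vehicle library of batch C, that library is assumed to vary like the other groups.

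Of 597 values of named genes with the vehicle pair factor, 426 kept direction and call, and 153 kept direction alone. Another 11 that were called neither with nor without the factor turned. So did 5 with a call in at least 1 of these fits: Nupr1 -0.04 for MEP day 7 against day 3, Notch1 -0.97 for MEP day 7 less ruxolitinib, and Ranbp1 -0.38, Serp1 -0.29 and Uqcrfs1 -0.66 for MEP batches. Without MEP ruxolitinib replicate 1 the rises of Hspa1a and Hspa1b under ruxolitinib turned to -0.73 and -0.36, with ranges over the libraries left out of -0.73 to 3.03 and -0.36 to 2.69. No other named value turned where it was called in the report or in the alternative. Values called in neither also turned, among them 13 with the GC offset, 10 in voom and 86 when leaving out libraries. Calls were lost, with direction kept, for 14 of 857 values with RLE, 9 of 836 in DESeq2, 6 of 857 without a filter, 46 of 857 with the replicate block, 9 of 71 with the animal number as block and 161 of 857 in voom. They were lost for 50 of 597 over expressed genes, 50 of 596 with the GC offset, 115 of 845 with the compared groups alone, 13 of 321 with pooled vehicles and 806 of 6883 when leaving out libraries. Simulated changes of 2 on the log2 scale were recovered by edgeR in 18.5% of cases on average for LSK ruxolitinib, with 2 vehicle libraries, against 77.3% for MEP ruxolitinib, with 3. Whether the depth, number or spread of the libraries sets this was not tested.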

Other observations

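The search for genes switched between treatments was chosen only after its gene had been seen, and the gene and list tests were planned.

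Some genes of other lists also changed in MEP cells. Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, rose at day 3 (2.4 ± 0.31, SE), at day 7 (1.07 ± 0.31) and under ruxolitinib (1.65 ± 0.32), from 4.9 ± 1.27 CPM under vehicle to 25.9 ± 2.72 at day 3 (SD, n = 3 and 4). Dusp6, a phosphatase of the ERK kinases, rose at day 7 (1.43 ± 0.42). The list of MEK and ERK output genes did not pass in these comparisons, with 1 of 19 members higher at day 3, 3 higher and 1 lower adjusted over the list alone, and a camera adjusted p of 0.0512, and adjusted p = 0.524 with an estimated correlation. Among the 8161 genes expressed in MEP cells 1663 were lower at day 7. MYC target and ribosome biogenesis genes fell in 11 of 40 cases at day 7, and in 23 adjusted over the list alone (camera adjusted p = 6.44e-11, and adjusted p = 0.286 with an estimated correlation). Of these Ranbp1 fell by 3.01 ± 0.39 at day 7 and rose by 1.1 ± 0.37 under ruxolitinib, beside a shift of 1.28 between vehicle batches. Under ruxolitinib the cell cycle inhibitor gene Cdkn1a, a p53 target, fell by 4.09 ± 0.91, with 11 of 24 p53 targets lower over all genes and adjusted over the list alone, a list that did not pass (camera adjusted p = 0.566, and adjusted p = 0.907 with an estimated correlation). Of all 25274 genes tested 9737 were lower in that comparison.

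A single gene switched with a treatment in both cell types. The transcript 3830403N18Rik had 98.4 to 105 CPM in the LSK and 74.7 to 127 CPM in the MEP libraries under ruxolitinib, and at most 0.971 and 0.627 CPM in all other libraries of those cells. Its fitted log2 changes were 9.92 ± 0.81 and 11.11 ± 0.58 (SE). In counts these were 2754 to 5221 and 3428 to 5099 against 1 to 13 and 0 to 9. With a minimum of 10 CPM in every library of a treatment and under 1 CPM in every other library, it was the 1 gene found among 33924 for ruxolitinib. The rule was met by 0 genes for tamoxifen day 3, tamoxifen day 7 or either vehicle batch. With the rule reversed, 0 genes were absent in every library of a treatment and present in all others. These counts rest on thresholds and not on a test. Which animals gave the ruxolitinib libraries is not given in the sources used here, so the ruxolitinib comparisons do not separate the drug from a difference of animals.

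Odorant and pheromone receptor genes, 1682 in the table, took 0.103% ± 0.0503 of counts in LSK vehicle A (SD, n = 4), 0.112% ± 0.0491 at tamoxifen day 3 (n = 3), 0.0984% ± 0.0142 at day 7 (n = 4), 0.0395% ± 0.0335 in LSK vehicle C (n = 2) and 0.0189% ± 0.0167 under ruxolitinib (n = 3). In MEP cells they took 0.052% ± 0.0143 in vehicle A (n = 3), 0.0552% ± 0.02 at tamoxifen day 3 (n = 4) and 0.125% ± 0.0578 at day 7 (n = 3).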
